A study of Homo sapiens with 39 samples.

How the data were processed

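Polyadenylated RNA of MCF-7 cells, an established estrogen receptor alpha-positive human breast cancer line, was measured by single-cell RNA sequencing on C1-HT microfluidic chips with Nextera XT indexing, per the labels' protocols. Per the labels, the cells were kept for 3 days in phenol-red-free medium with charcoal-stripped serum, stained with CellTracker dyes and treated with ethanol or estradiol (E2); the dose was not given in the sources used here. Each sample's label gives only a time and not whether it had ethanol or estradiol, so 12 h is read as 12 h of estradiol from the series alone. The labels give 39 samples, each of which is 1 column of a chip holding up to 40 cells: 19 columns at 0 h (column 4 of that chip is not analysed here) and 20 columns at 12 h. All columns of one time came from 1 chip and the labels name no separate cultures, so p-values measure only the spread between columns of a chip, and chip and time cannot be told apart.

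The values are FPKM (fragments per kilobase of gene per 1000000 mapped fragments), deposited as 1 table of 57536 gene rows (112 with a repeated identifier) and 1122 cell columns. Reads were aligned with TopHat2 2.0.6 to hg19, per the submitters' processing notes; the program that turned alignments into FPKM, the treatment of reads with several alignments and the use of strand are not given in the sources used here. Reads shared between a gene and its pseudogene or an overlapping gene may therefore be divided in a way that cannot be checked. Column names were matched to samples by time and chip column; the name of the 0 h column 19 carries the number of the other chip, and its time was taken from the stated time. The table of 40 row barcodes was not used. Gene symbols, identifiers and coordinates are those of the deposited table, in hg19, written 1-based. GENCODE 29, which is built on another genome build, was used only to look up gene types by Ensembl identifier, which succeeded for 95.3% of the tested genes.

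FPKM hides depth, so total reads per cell are unknown. The lowest values of rarely listed genes (5343 genes listed above 0 in 1 to 6% of cells) clustered at steps: 42.1% lay within 0.15 on the log2 scale of the value of 1 read and 62.6% within 0.15 of 1 to 4 reads. The position of the lowest step gave a relative depth for 1118 cells, scaled to a median of 1; the steps were too blurred to recover whole reads, and no count model was run. Kept cells numbered 516 at 0 h and 604 at 12 h, after removal of 2 cells (both at 12 h) with fewer than 1000 genes above 0. Kept cells listed 1166 to 10206 genes above 0, and their FPKM summed to 641841 to 2894010.

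The unit of the tests between the times was the chip column and not the cell, except in the depth-matched comparison given near the end. That comparison pools pairs of single cells over columns and ranks the list among random lists. The p-values of co-variation against random lists also rank gene lists, by means over columns. For each column the FPKM of its kept cells were averaged, and log2(mean + 1) was compared between the times with limma 3.58.1 (linear model, empirical Bayes with trend, two-sided) in R 4.3.3 for the 14619 genes with a mean of at least 1 FPKM over the columns. Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05, and differences are on the log2(FPKM + 1) scale, which understates changes of low genes. A second count required at least a 1.5-fold difference. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list moves one way without comparing it with other genes. Of 28 lists, the 23 with at least 5 tested members entered: estrogen-induced, estrogen-repressed, one-carbon and serine, polyamine, purine and pyrimidine synthesis, ribosome biogenesis, cytosolic ribosomal proteins, G1/S, G2/M, cholesterol synthesis, glycolysis, nuclear-encoded respiratory chain, amino acid supply, endoplasmic reticulum folding, cytosolic chaperones, immediate-early, hypoxia, p53 and apoptosis, interferon, luminal epithelium, mitochondrial mRNA and nuclear long noncoding RNA. The other 5 hold markers of basal, fibroblast, immune, endothelial and erythroid cells.

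Genes detected per cell, the share of cells listing each of 20 fixed genes and the level among those cells were compared over columns by two-sided permutation tests with 100000 resamples in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). Co-variation of 4 lists was the Spearman rho across the kept cells of a column between list scores (the mean z-score of log2(FPKM + 1) over members), averaged over columns with at least 10 cells and set against 1000 pairs of random lists matched on size and expression, with 6 list pairs at each time. On simulated data of the same size and spread, limma recovered 44% of genes raised 1.5-fold, 72% of those raised 2-fold and 40% of those lowered 1.5-fold, and called 4 of 14419 genes that had not been changed. The simulation drew columns independently and put the full fold into the mean of every 12 h column. In the data most cells stood at matching chip positions, described below. These percentages therefore do not give the recovery of a change present only in the other cells. The co-variation test recovered a planted relation of polyamine with purine genes at each of the 2 times and called 0 of 10 others. Each gene had been shuffled over the cells of a column, which removes co-variation from depth. The 0 of 10 therefore does not cover false calls that depth could give.

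Named genes followed a rule: the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 10 FPKM and one direction under every scaling, 20 genes named whatever their values, and in each described list up to 4 members past the threshold with the smallest adjusted p and up to 2 that went against the majority. The design, the lists, this rule and the alternatives for cell filter, gene filter, pseudocount, scaling, summary over cells, column block, chip part, column weights and left-out columns were fixed before the data were examined. The comparisons by chip position, those without columns 4 and 19, the depth covariate, the block with an estimated correlation or fry, and the sign-flip tests paired by column were added after the data were seen. For positions listed at one time the same naming rule was applied afterwards, without its condition on scaling.

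Column numbers are shared between the times. Deviations from the mean of the time correlated at 0.361 to 0.463 between columns of the same number, in each of 19 pairs, and at no more than 0.0569 between other numbers. Single profiles in the same column and another row had a median r of 0.0014 between the times, against 0.757 at the same row. The pairing thus goes mainly with the matching chip positions described below, whose cause stays open, and is no known pairing of cultures. Fits with the column number as a block and tests paired by column rest on that match. The block fit is printed beside the main counts of genes and lists. Profiles of all listed cells were also compared between the times by chip position (column and row): Pearson r of log2(FPKM + 1), centred by gene over the cells of both times, for 5974 genes with a mean log2 value above 2. Figures were drawn with matplotlib 3.10.9.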

Results

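Single MCF-7 cells, from a breast cancer line that depends on the estrogen receptor, were profiled at 0 h and at 12 h of the estradiol experiment. The series asks whether estrogen signalling raises one-carbon, polyamine and purine synthesis together. Kept cells numbered 27.2 ± 2.4 per chip column at 0 h (SD, n = 19 columns) and 30.2 ± 2.7 at 12 h (n = 20). The median cell of a column listed 7397 ± 222 genes above 0 at 0 h and 7380 ± 479 at 12 h, a difference of -16.3 (permutation test, p = 0.911). In columns 1 to 10 the difference was -177 (n = 9 and 10, permutation p = 0.502) and in columns 11 to 20 it was 147 (permutation p = 0.269). The 12 h column 4, which has no 0 h partner, listed 5691 genes; without it the difference was 72.6 over the chip (permutation p = 0.375) and -9.56 in columns 1 to 10 (permutation p = 0.915). Paired by column number, 17 of 19 columns were higher at 12 h (mean difference 72.6 ± 159 SD, sign-flip p = 0.0630). Mitochondrially encoded genes took 15.3 ± 1.5% of FPKM at 0 h and 15.3 ± 1.8% at 12 h. Reads per cell are unknown, and every n given with an SD is a number of chip columns.

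Over all kept cells, genes known to be induced by estradiol were slightly higher at 12 h as a group, and genes known to be lowered by it were slightly lower. Of these cells, 408 of 516 at 0 h and 408 of 604 at 12 h stood at chip positions whose profiles matched between the times, as described below. The mean log2 difference of the estrogen-induced list relative to all genes was 0.0029 there and 0.67 at the other positions. Differences over all kept cells are thus diluted by the matching positions. The 51 tested members of the estrogen-induced list had a median log2 difference of 0.17, against 0.014 for all genes (camera, adjusted p = 5.6e-12, or adjusted p = 0.0052 with an estimated correlation and 0.014 with fry). The 29 members of the estrogen-repressed list had a median of -0.099 (camera, adjusted p = 1.7e-04, or adjusted p = 0.0071 with an estimated correlation and 0.143 with fry). The 42 G1/S genes, which peak as cells enter DNA replication, had a median of 0.14 (camera, adjusted p = 2.2e-07, but adjusted p = 0.183 with an estimated correlation). The 22 cytosolic chaperones had a median of 0.060 (camera, adjusted p = 2.7e-04, but adjusted p = 0.232 with an estimated correlation). The 14 pyrimidine synthesis genes had a median of 0.091 (camera, adjusted p = 0.0271, but adjusted p = 0.232 with an estimated correlation). In these 5 lists 0 members passed limma over all genes tested and 0 passed adjusted over the list alone. With the column number as a block, 12 estrogen-induced, 7 G1/S, 4 pyrimidine and 3 chaperone genes were higher adjusted over the list alone, 2 estrogen-repressed genes were lower, and 2 estrogen-induced genes passed over all genes tested.

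Among single genes, 2 of 14619 were higher at 12 h and 0 were lower (limma, adjusted p below 0.05), both by at least 1.5-fold, and 265 genes had an unadjusted p below 0.05. RP11-175B9.3 (ENSG00000236439.3, chromosome 1, 202440937 to 202441258 in hg19), a processed pseudogene, rose from 12.3 ± 4.9 to 23.4 ± 6.1 FPKM (SD, n = 19 and 20), a log2 difference of 0.93 ± 0.16 (SE, limma adjusted p = 0.0082). KRT18P10 (ENSG00000214207.2), a processed pseudogene of the keratin gene KRT18 with which it can share reads, was higher by a log2 difference of 0.61 ± 0.12 (SE, limma adjusted p = 0.0442), a call lost when any of 24 single columns was left out. It lies below the 10 FPKM of the naming rule and is named after its value was seen. Of the 20 fixed genes, 0 passed. GREB1, a cofactor of the estrogen receptor, was at 55.4 ± 8.2 and 64.9 ± 10.9 FPKM. TFF1, a secreted estrogen target, was at 18607 ± 3266 and 21102 ± 3281 FPKM, and PAICS, a purine synthesis enzyme, was at 37.4 ± 9.2 and 45.9 ± 11.6 FPKM (limma adjusted p = 0.99997 for each).

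With the chip column number as a block, 7 genes were higher and 2 lower. The higher ones were RP11-175B9.3, KRT18P10, RP11-380M21.2, TPD52L1, RPS25, TFF1 and TOMM5, and the lower ones CHD6 and DNAJC4. TFF1 then differed by a log2 value of 0.16 ± 0.027 (SE, limma adjusted p = 0.0291) and TPD52L1, another member of the estrogen-induced list, by 0.24 ± 0.038 (adjusted p = 0.0291). In chip columns 1 to 10, and likewise in columns 11 to 20, limma called 0 genes higher and 0 lower, with 195 and 191 genes at an unadjusted p below 0.05.

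The lists that the series is about did not pass over all kept cells, most of which stood at the matching positions. The 24 one-carbon and serine genes had a median log2 difference of 0.067 (camera, adjusted p = 0.0754). The 14 polyamine genes had one of 0.012 (adjusted p = 0.261), below the all-gene median although their mean of 0.047 lay above it. The 19 purine synthesis genes had one of 0.029 (adjusted p = 0.258). With the column number as a block the one-carbon list passed (camera, adjusted p = 0.0364), as did ribosome biogenesis (0.0314), the nuclear-encoded respiratory chain (0.0068) and mitochondrial mRNA (0.0183). None of these 4 passed with the block and an estimated correlation (adjusted p = 0.0540, 0.287, 0.287 and 0.413), under which the 5 lists of the fit without block did, G1/S at an adjusted p of 0.0188. Without the block, adjusted p was 0.0754 for ribosome biogenesis, G2/M and the respiratory chain. It was 0.140 for p53 and apoptosis, 0.182 for hypoxia, 0.204 for nuclear long noncoding RNA and 0.221 for endoplasmic reticulum folding. Cytosolic ribosomal proteins, at 0.258, passed as lower with cells rescaled to 1000000 (0.0371) and with median-of-ratios scaling (0.0041). Adjusted p was also 0.258 for amino acid supply, interferon and mitochondrial mRNA, 0.270 for glycolysis, 0.283 for luminal epithelium, 0.631 for immediate-early genes and 0.997 for cholesterol synthesis.

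Profiles at the same chip position matched between the times. A position, meaning a column and a row, could have a cell column in the table at both times or at one time. There were 408 positions listed at both, where independent filling would give 390 of the 760 positions in the shared columns. At each of these 408 positions the library labelled 0 h correlated best, of all 12 h profiles, with the library labelled 12 h at the same position. The mean r per column was 0.759 ± 0.035 (SD, n = 19), and r of single positions ran from 0.611 to 0.921. Profiles in the same column and another row had a median r of 0.0014, those in the same row and another column one of 0.0019, and the highest r of any libraries at different positions was 0.356. Libraries at one position shared 77.7 ± 1.5% of their detected genes (SD, n = 19 columns), and in 0 of the 408 pairs were the values identical. The log number of genes detected correlated between the libraries of a position at r = 0.999. The remaining 108 cells at 0 h and 196 cells at 12 h stood at positions listed at one time, 30 of the latter in column 4, which has no 0 h sample here.

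**Figure D1:**
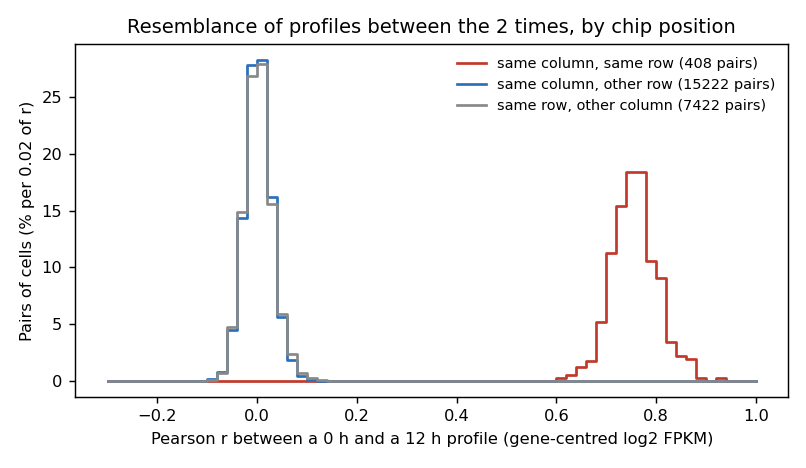
Distribution of Pearson r between a 0 h and a 12 h profile (horizontal axis, gene-centred log2 FPKM) as a percentage of the pairs in each class (vertical axis). The 408 pairs at the same column and row (red) lie between 0.611 and 0.921, whereas pairs that share only the column (blue) or only the row (grey) centre near 0.

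Where positions were listed at one time, chosen as a comparison after the data were seen, estradiol target genes were higher at 12 h as a group. These columns held few cells, and each counted equally in the fit. They numbered 5.7 ± 1.9 per column at 0 h (SD, range 1 to 8) and 9.8 ± 5.4 at 12 h (range 4 to 30). GREB1 (ENSG00000196208.9, chromosome 2, 11674242 to 11782914 in hg19) rose from 37.1 ± 20.6 to 72.3 ± 24.2 FPKM (SD, n = 19 and 20 columns), a log2 difference of 1.08 ± 0.20 (SE, limma adjusted p = 0.0166). TFF1 (ENSG00000160182.2, chromosome 21, 43782391 to 43786703) rose from 15353 ± 4958 to 23553 ± 5115 FPKM (log2 difference 0.66 ± 0.13, adjusted p = 0.0233). PGR, the progesterone receptor (ENSG00000082175.10, chromosome 11, 100900355 to 101001255), rose from 3.34 ± 2.30 to 8.36 ± 5.30 FPKM (log2 difference 1.10 ± 0.25, adjusted p = 0.0401). CXCL12, a chemokine (ENSG00000107562.12, chromosome 10, 44793038 to 44881941), rose from 0.574 ± 0.863 to 5.67 ± 6.72 FPKM (log2 difference 1.63 ± 0.35, adjusted p = 0.0307). The estrogen-induced list had a median log2 difference of 0.70 against 0.22 for all genes (camera, adjusted p = 2.4e-17, or 1.8e-05 with an estimated correlation). Of its 51 members 11 rose over all genes tested (5 with the column number as a block) and 27 adjusted over the list alone, and 0 fell on either count. RAB31, a small GTPase, led by adjusted p, with a log2 difference of 1.07 ± 0.19 (adjusted p = 0.0107). The fixed members MYC, CCND1 and XBP1 did not pass, with log2 differences of 0.42, 0.053 and 0.39 (limma adjusted p = 0.548, 0.953 and 0.210).

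**Figure D2:**
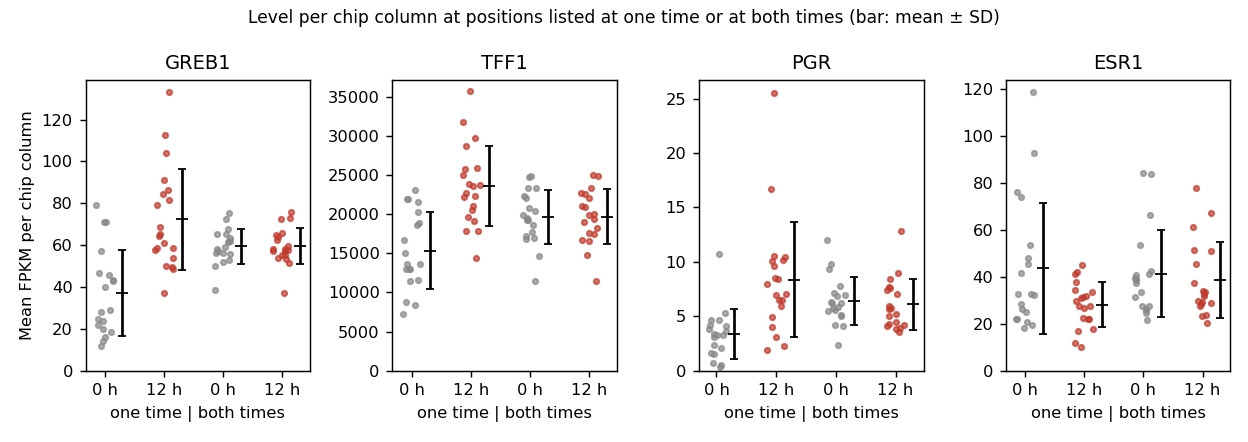
Mean FPKM per chip column (vertical axes, each starting at 0) of GREB1, TFF1, PGR and ESR1 at 0 h (grey) and 12 h (red), for positions listed at one time and at both times; black bars are the mean ± SD over columns. At positions listed at one time GREB1 went from 37.1 to 72.3 FPKM, and at positions listed at both times it was 59.6 at each time.

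Those positions gave 74 genes higher and 3 lower (limma, adjusted p below 0.05), 66 of them by at least 1.5-fold. The median log2 difference of all genes was 0.22, and these counts were not taken relative to it. Genes of at least 10 FPKM are listed here by the fitted log2 difference, which averages the logs of columns and can be inflated where columns were at 0. FPKM also divides by gene length. In short genes such as VTRNA1-3 (chromosome 5, 140105743 to 140105831 in hg19) few reads can thus give a high value. The vault RNA VTRNA1-3 went from 5893 ± 6230 to 15774 ± 10718 FPKM (log2 difference 6.02 ± 1.49 SE, but 1.42 from the means, with 8 columns at 0 at 0 h). The small nucleolar RNA SNORA57 (ENSG00000206597.1) went from 27.2 ± 76.7 to 310 ± 426 (4.46 ± 1.08, 3.51 from the means, 14 columns at 0), IFRG15 from 20.5 ± 61.7 to 55.5 ± 49.0 (3.81 ± 0.66, but 1.44 from the means, 12 columns at 0) and RN7SL674P from 27.7 ± 39.4 to 62.0 ± 43.9 (2.78 ± 0.68, but 1.16 from the means, 9 columns at 0). RP3-468B3.3 went from 3.98 ± 5.47 to 29.3 ± 34.1 (2.501 ± 0.54, 2.88 from the means, 8 columns at 0), POLG2 from 9.61 ± 13.1 to 38.9 ± 46.9 (2.48 ± 0.61, 2.02 from the means, 9 columns at 0) and FAM129B from 9.58 ± 18.5 to 17.2 ± 13.7 (2.20 ± 0.54, but 0.84 from the means, 8 columns at 0). WDR76 (2.12 ± 0.45, 1.496 from the means, 3 columns at 0) is given below. ALDH16A1 went from 11.1 ± 17.4 to 26.3 ± 15.8 (2.04 ± 0.47, 1.24 from the means, 3 columns at 0) and NPY1R, a neuropeptide Y receptor, from 4.80 ± 5.44 to 21.8 ± 18.2 (1.96 ± 0.48, 2.18 from the means, 4 columns at 0). Of the decreases, CHD6, a chromatin remodeller, fell from 322 ± 105 to 192 ± 86 FPKM (log2 difference -0.77 ± 0.17, limma adjusted p = 0.0307). ARID4A fell from 89.1 ± 38.7 to 51.2 ± 15.9 FPKM (-0.72 ± 0.18, adjusted p = 0.0499). AC092301.3, the remaining one, had a mean of 1.06 FPKM and is named after its value was seen. Without column 4 the count was 24 higher and 2 lower, and with the column number as a block 24 higher and 1 lower. With column 4 left out as well, equal numbers of cells at both times in each column, drawn once, gave 0 and 0, with 1063 genes at an unadjusted p below 0.05 against 1786 without column 4 alone and 1961 with it. The 74 genes called higher, chosen for their rise, had a median log2 difference of 1.34 (median SE 0.31), which was 1.35 (0.32) without column 4 and 1.08 (0.38) with equal cell numbers, all 74 above 0 in each fit. The median of all genes was 0.22, 0.21 and 0.059 in these fits. Among the targets named above that had passed, PGR did not pass without column 4 and CXCL12 did not pass with the block. With equal cell numbers none of GREB1, TFF1, PGR and CXCL12 passed. The estrogen-induced list passed camera in each of these settings, with an adjusted p of 8.2e-17 without column 4, 1.2e-16 with the block and 5.1e-18 with equal cell numbers (median log2 difference 0.73, against 0.059 for all genes).

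Lists of cell cycle entry, pyrimidine synthesis and ribosome biogenesis passed camera at these positions, each with few members past the threshold. Of the 42 G1/S genes 3 rose over all genes tested and 9 adjusted over the list alone, with a median log2 difference of 0.67 (camera, adjusted p = 1.1e-08, but adjusted p = 0.0642 with an estimated correlation). UNG, a uracil DNA glycosylase, rose from 40.05 ± 30.2 to 106 ± 57 FPKM (limma adjusted p = 0.0307). WDR76 rose from 11.1 ± 13.6 to 31.2 ± 16.2 FPKM (adjusted p = 0.0307) and CDCA7 from 3.85 ± 6.61 to 8.59 ± 5.24 FPKM (adjusted p = 0.0458). Of the 14 pyrimidine synthesis genes 2 rose over all genes tested and 7 adjusted over the list alone (median 0.80, camera, adjusted p = 4.8e-05, or 0.0446 with an estimated correlation). CTPS1, which makes CTP, rose from 13.1 ± 13.05 to 33.6 ± 17.2 FPKM (limma adjusted p = 0.0307), and DCTPP1 rose from 193 ± 55 to 260.3 ± 41.1 FPKM (adjusted p = 0.0401). Of the 39 ribosome biogenesis genes 2 rose over all genes tested, NOP16 (149 ± 54 to 245 ± 67 FPKM, adjusted p = 0.0307) and NPM1 (2106 ± 354 to 2644 ± 477 FPKM, adjusted p = 0.0436), and 9 adjusted over the list alone (median 0.46, camera, adjusted p = 9.6e-05, or 0.0446 with an estimated correlation). With the column number as a block 1 G1/S, 1 pyrimidine and 0 ribosome biogenesis genes passed over all genes tested, and 9, 7 and 6 adjusted over the list alone.

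The one-carbon, polyamine and purine lists did not pass camera at these positions in the fit used here. The one-carbon and serine list had a median log2 difference of 0.44 (adjusted p = 0.0612). It had 0 of 24 members past the threshold over all genes tested and 4 higher adjusted over the list alone, among them MTHFD2, a mitochondrial folate enzyme (54.4 ± 29.4 and 77.8 ± 22.2 FPKM). The polyamine list had a median of 0.32 (adjusted p = 0.176), with 0 of 14 on either count. The purine list had a median of 0.25 (adjusted p = 0.436). It had 0 of 19 over all genes tested and 6 higher adjusted over the list alone, among them GART (41.2 ± 26.8 and 64.5 ± 20.6 FPKM) and PAICS (31.2 ± 16.2 and 49.3 ± 24.2 FPKM). The one-carbon list passed with equal cell numbers (camera, adjusted p = 0.0493) and with the mean of log2 over cells (0.0472), under which the polyamine list also passed (0.0426) and the purine list did not (0.108). With an estimated correlation adjusted p was 0.183, 0.263 and 0.683 for the 3 lists. By fry, which does not set a list against other genes, adjusted p was 1.9e-04 for one-carbon, 6.2e-04 for polyamine and 0.0090 for purine, where the median of all genes lay at 0.22. Of the other fixed genes ODC1, the first enzyme of polyamine synthesis, was at 8.92 ± 6.61 and 11.7 ± 5.1 FPKM. SRM was at 182 ± 105 and 202 ± 65 and AMD1 at 34.8 ± 21.4 and 45.8 ± 17.1. PHGDH was at 13.9 ± 10.2 and 16.04 ± 7.05, SHMT2 at 28.9 ± 20.9 and 28.1 ± 8.7 and PPAT at 20.6 ± 13.3 and 21.7 ± 11.2. None of these passed the threshold (limma adjusted p of 0.348 or more).

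Other lists moved at these positions too. The 22 chaperones passed (camera, adjusted p = 5.6e-05, or 0.0388 with an estimated correlation), with 0 members past the threshold over all genes and 9 higher adjusted over the list alone. Glycolysis passed with TPI1 higher (930 ± 238 to 1173 ± 159 FPKM; camera, adjusted p = 0.0103, but adjusted p = 0.0922 with an estimated correlation). The nuclear-encoded respiratory chain passed upward (camera, adjusted p = 0.0326, but adjusted p = 0.447 with an estimated correlation) although its median of 0.14 lay below the all-gene median of 0.22; its one called member was NDUFB9 (1257 ± 241 to 1542 ± 200 FPKM). The estrogen-repressed list was lower (median -0.081, camera, adjusted p = 4.7e-05, or 0.0297 with an estimated correlation, and 0.256 with fry), with 0 of 29 members past the threshold and 1 lower adjusted over the list alone. Lower relative to all genes were luminal epithelium (median -0.052, adjusted p = 0.0025, but adjusted p = 0.0642 with an estimated correlation) and mitochondrial mRNA (median -0.0078, adjusted p = 0.0103, but adjusted p = 0.453 with an estimated correlation). So was nuclear long noncoding RNA (median -0.22, adjusted p = 0.0012, or 0.0446 with an estimated correlation). With equal cell numbers the luminal (adjusted p = 0.32) and mitochondrial (adjusted p = 0.46) calls were lost. ESR1, the estrogen receptor gene, was at 43.7 ± 27.9 and 28.2 ± 9.7 FPKM. MYC was at 41.5 ± 26.1 and 48.1 ± 19.5, CCND1 at 558 ± 228 and 565 ± 209 and XBP1 at 456 ± 186 and 582 ± 171. MKI67 was at 181 ± 85 and 211 ± 71, CCNG2 at 12.1 ± 10.7 and 8.56 ± 7.09, and ERBB2 at 8.24 ± 10.16 and 4.58 ± 4.62. None of these passed the threshold.

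**Figure D3:**
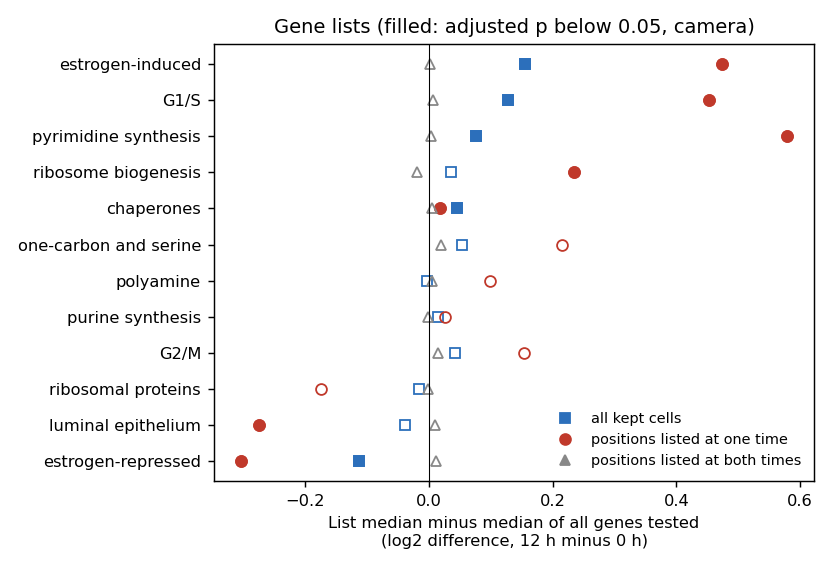
Median log2 difference (12 h minus 0 h) of each of 12 gene lists minus the median of all genes tested (horizontal axis), over all kept cells (squares), positions listed at one time (circles) and positions listed at both times (triangles); filled symbols passed camera at an adjusted p below 0.05. For the estrogen-induced list the raw medians were 0.17, 0.70 and 0.0018.

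At the 408 positions listed at both times the libraries labelled 0 h and 12 h hardly differed. The estrogen-induced list had a median log2 difference of 0.0018 (camera, adjusted p = 0.927). GREB1 was at 59.6 ± 8.4 and 59.6 ± 8.8 FPKM, TFF1 at 19631 and 19664 FPKM and PGR at 6.43 and 6.10 FPKM. Mitochondrial mRNA was the one list past the threshold, with a median of 0.035 (camera, adjusted p = 0.0204, lost with an estimated correlation, under which 0 lists passed). Limma called the 2 genes named above, RP11-175B9.3 and KRT18P10, and with the column number as a block 10 genes higher and 4 lower. The higher ones included MT-CO3 (log2 difference 0.042 ± 0.0040, adjusted p = 2.5e-05) and the processed pseudogene MRPL53P1 (1.01 ± 0.15, adjusted p = 0.0046), and the lower ones were AKR1B1, RPL10, PSMA7 and PTMA. RP11-175B9.3 differed at positions listed at one time by a log2 value of 2.16 ± 0.59 (SE, limma adjusted p = 0.0779).

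The same positions differed in depth. Cells at positions listed at both times listed a median of 7489 genes at 0 h and 7533 at 12 h, with a relative depth of 1.03 and 1.05. At positions listed at one time the medians were 5777 genes at 0 h and 6682 at 12 h outside column 4, with relative depths of 0.558 and 0.846, and column 4 listed 5691 genes at a relative depth of 0.633. Averaged over columns, positions listed at one time had 6051 ± 994 genes at 0 h and 6846 ± 916 at 12 h (permutation p = 0.0144), and those listed at both times differed by 26.4 genes (permutation p = 0.783). Paired by column number, the differences were 856 genes (sign-flip p = 0.0109) and 26.4 genes (sign-flip p = 0.0024), each higher at 12 h in 14 of 19 columns.

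The share of cells listing a fixed gene and the level in those cells were compared next. Over all kept cells 0 of 20 shares differed, with 2 at an unadjusted p below 0.05 (permutation test), and 1 level did. GREB1 was at a log2 FPKM of 5.22 ± 0.30 at 0 h and 5.53 ± 0.25 at 12 h among the cells listing it (permutation, adjusted p = 0.0070). In columns 1 to 10 and 11 to 20, with fewer columns, the difference was alike at 0.29 and 0.32 (unadjusted p = 0.0240 and 0.0113) but did not pass adjusted, whereas at positions listed at both times it was -0.0095. Paired by column number, the shares of GREB1, PGR and CXCL12 were higher (sign-flip, adjusted p = 0.0337, 0.0282 and 0.0282), the levels of GREB1, TFF1 and XBP1 were higher (adjusted p = 0.0038, 0.0038 and 0.0377) and that of ESR1 was lower (adjusted p = 0.0103). In the cells of positions listed at one time 3 shares were higher at 12 h, and 5 were when paired by column number. GREB1 was listed in 82.7 ± 15.99% and 97.9 ± 4.7% of cells, PGR in 62.0 ± 15.2% and 84.4 ± 10.2%, and CXCL12 in 7.42 ± 9.43% and 22.4 ± 11.9% (permutation, adjusted p = 0.0014, 2.0e-04 and 0.0011). The level among listing cells was higher for GREB1 (4.18 ± 0.78 and 5.65 ± 0.55), TFF1 (13.47 ± 0.70 and 14.20 ± 0.36) and XBP1 (8.34 ± 0.59 and 8.86 ± 0.39; permutation, adjusted p = 2.0e-04, 0.0015 and 0.0171). Depth was also higher at 12 h there. Median shares were 3.25 and 4.16% for basal, 5.43 and 5.79% for fibroblast, 0.768 and 0.486% for immune and 1.63 and 0.417% for endothelial markers. The highest share in a list went from 26.7 to 41.9% of cells for basal (MYLK) and from 50.7 to 54.4% for fibroblast markers (FN1). It went from 3.64 to 7.16% for immune (LYZ), from 16.9 to 15.7% for endothelial (EMCN) and from 0.752 to 0% for erythroid markers (HBA1).

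Markers of other cell types gave the background over all kept cells. Their median share of cells was 4.66 and 4.76% for basal, 6.93 and 7.69% for fibroblast, 0.881 and 0.721% for immune, 0.950 and 0.621% for endothelial and 0.195 and 0.192% for erythroid markers, at 0 h and 12 h. The most abundant were FN1, at 21.1 ± 13.4 and 20.03 ± 10.9 FPKM and listed in 61.2 and 62.0% of cells, MYLK at 4.46 ± 3.72 and 6.13 ± 5.22 FPKM, and EMCN at 6.02 ± 5.09 and 5.82 ± 4.75 FPKM. LYZ, the most abundant immune marker, stood at 0.454 and 0.391 FPKM and HBA1 at 0.044 and 0.045 FPKM.

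Across single cells of a column, one-carbon and purine synthesis genes went up and down together. The mean Spearman rho of their scores was 0.591 ± 0.130 at 0 h (SD, n = 19 columns) and 0.539 ± 0.142 at 12 h (n = 20), above all of the 1000 matched random pairs at each time, whose middle 95% ended at 0.424 and 0.386 (p = 0.0020, the smallest these can give, adjusted p = 0.0060). One-carbon with polyamine genes had 0.417 ± 0.175 and 0.355 ± 0.154 (adjusted p = 0.0679 and 0.127), and polyamine with purine genes 0.394 ± 0.200 and 0.348 ± 0.195 (adjusted p = 0.168 at both times). With ranks within a cell one-carbon with polyamine genes lay above random lists at both times (rho of 0.223 and 0.157, adjusted p = 0.0080 and 0.0420). With genes detected held fixed it did so at 12 h (0.187, adjusted p = 0.0240), as did polyamine with purine genes (0.193, adjusted p = 0.0480). The estrogen-induced score followed the one-carbon score at 0.338 ± 0.224 at 0 h and 0.131 ± 0.140 at 12 h, lower by -0.207 (permutation, adjusted p = 0.0074), and the purine score at 0.303 ± 0.231 and 0.133 ± 0.136 (difference -0.170, permutation, adjusted p = 0.0229). At 12 h both values lay below all random pairs (adjusted p = 0.0060). With the polyamine score it was 0.309 ± 0.228 and 0.221 ± 0.213 (permutation, adjusted p = 0.295 for the difference). Paired by column number, these 2 differences had an adjusted p of 0.0013 each (sign-flip), and 2 more pairs were lower at 12 h, estrogen-induced with polyamine and one-carbon with purine (adjusted p = 0.0431 each). Using ranks within a cell, 0 pairs lay below random lists, and the 2 differences were -0.157 and -0.128 (permutation, adjusted p = 0.0554 and 0.117). With genes detected held fixed they were 0.021 and 0.0098 (adjusted p = 0.862 and 0.865). At positions listed at both times 0 pairs differed. The 2 times are not independent at the positions listed at both.

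**Figure D4:**
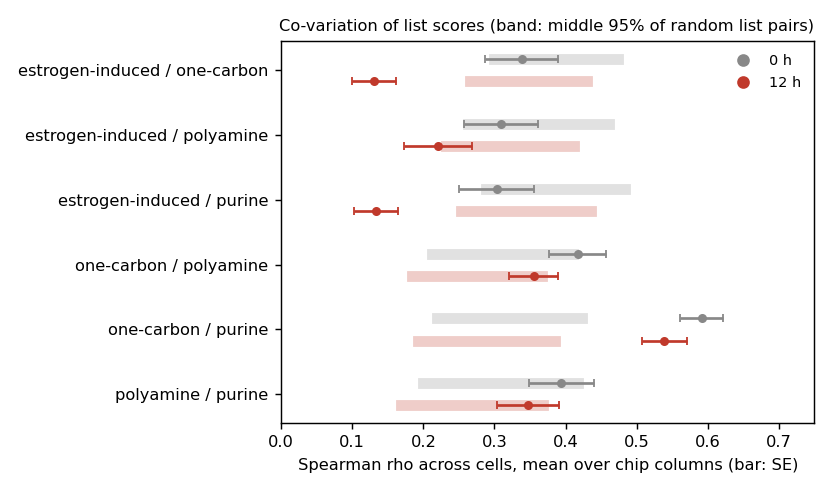
Mean Spearman rho across cells between list scores for 6 pairs of lists at 0 h (grey, n = 19 columns) and 12 h (red, n = 20); error bars are the SE over columns, and pale bands span the middle 95% of 1000 random list pairs. One-carbon with purine synthesis, at 0.591 and 0.539, lies to the right of its band at both times.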

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

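The split of chip positions and the test between them were chosen after the data were seen, as were the test of other differences between the chips and the count of other splits; the depth test had its prediction written before its result. The difference of the estrogen-induced list between 12 h and 0 h differed between the 2 kinds of chip position. Averaged over members and relative to the median of all genes in a column, it was 0.67 ± 0.32 on the log2 scale at positions listed at one time (SD, n = 19 columns, above 0 in 19 of 19) and 0.0029 ± 0.038 at positions listed at both times (above 0 in 10 of 19). The positions listed at one time exceeded the others by 0.67 in the mean and in 19 of 19 columns (sign-flip permutation test, p = 1e-05, the smallest these can give). The split was made after the match of profiles at positions listed at both times was seen, and a difference near 0 there goes with that match, so this p is not independent evidence of a response.

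Deeper wells at 12 h were tested as the source of the difference at positions listed at one time. In 86 pairs of cells matched within 0.1 log2 on relative depth, the list's median log2 difference was 0.44, where the middle 95% of 10000 random lists of like expression ran from -0.11 to 0.13, which places it at percentile 100. The pairs pooled cells over columns, column 4 was not left out, and random lists need not vary together as the list's members may. The percentile therefore measures no spread between columns. Within these limits it argues against depth and cell number as the whole cause of the list's difference. A difference between the chips other than time stays open and cannot be told apart from estradiol, because each time has 1 chip. In 100 splits of the columns, 1, the real one, gave as many as its 77 calls, and the highest of the others gave 2. Random division of the columns is thus excluded for that count in that fit. The splits were not repeated without column 4 or with equal cell numbers, and they do not address depth or cell number. The count was 24 higher and 2 lower without column 4 and 0 with equal cell numbers and no column 4. There the 74 genes called higher had a median log2 difference of 1.08 (median SE 0.38) against 1.34 (0.31) before. The median of all genes was 0.059 there against 0.22 before. The calls thus ended with a larger error and a smaller difference, part of that decrease being shared by all genes. An estradiol response may account for the difference of the list, with the chip left open. The depth-matched comparison covered the list alone. For the 74 genes, an estradiol response, depth, cell number and the chip all stay open.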

How the results depend on the processing

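The settings by chip position, those without columns 4 and 19, the depth covariate, the pairing by chip column and the replicate block with the estimated correlation or fry were chosen after seeing the data; the others were set beforehand. A change of sign was counted as a reversal only where one of the compared values passed its threshold; changes of sign with neither past it numbered 55 of 1318 single-gene values and 63 of 734 list values. For 21 results on single genes, 1295 of 1318 values stayed on their side of the threshold, those changes of sign included, 8 fell below it, 15 rose past it and 0 reversed. For 23 lists, 639 of 734 values stayed on theirs, those changes of sign included, 22 fell below, 56 rose past and 17 reversed. Except where stated, the cause was not tested.

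The number of genes higher at 12 h, 2 over all kept cells, was 1 with genes of at least 10 FPKM (KRT18P10 is then not tested), pseudocount 0.1, cells rescaled to 1000000, quantile normalization, without chip columns 4 and 19, and with relative depth as covariate. It was 0 with the median over cells, in chip columns 1 to 10 and in chip columns 11 to 20, where limma gave 181, 195 and 191 genes at an unadjusted p below 0.05 and where fewer genes or fewer samples entered. With the replicate block it was 7 higher and 2 lower. The number changed at least 1.5-fold, also 2, was 1 in those same 6 settings and with pseudocount 10 and the mean of log2 over cells, and 0 with the median over cells and in each of these chip parts. With the replicate block this number was 3. Leaving out single columns gave 1 to 3 genes for both counts. It gave 1 without 0 h columns 1, 3, 5, 6, 7, 8, 9, 12, 13, 17, 18, 19 or 20 and without 12 h columns 1, 2, 4, 6, 7, 8, 11, 12, 14, 15 or 16, and 3 without 12 h columns 10 or 19. RP11-175B9.3 passed in each of these fits.

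Positions listed at one time gave 74 genes higher and 3 lower, 66 of them at least 1.5-fold. Without chip column 4 these numbers were 24, 2 and 24, with the replicate block 24, 1 and 22, and with the mean of log2 over cells 97, 1 and 90. With equal cell numbers limma gave 0, 0 and 0 (1063 genes at an unadjusted p below 0.05 against 1786 without chip column 4), a setting that also leaves out chip column 4 and draws fewer cells at 12 h in most columns and at 0 h in some. At positions listed at both times with the replicate block 10 were higher and 4 lower.

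The number of lists past the threshold, 5, was 2 with the estimated correlation, 1 with fry, 8 with the mean of log2 over cells and 9 with the replicate block (5 with the block and the estimated correlation, 6 with the block and fry). It was 6 with cells rescaled to 1000000 and with median-of-ratios scaling, where cytosolic ribosomal proteins passed as lower (0.0371 and 0.0041). With the median over cells it stayed at 5, pyrimidine synthesis and chaperones being lost (0.0690 each) and G2/M (0.0169) and nuclear long noncoding RNA (0.0045, lower) passing. In chip columns 1 to 10 it was 5, with p53 and apoptosis (0.0284) in place of the estrogen-repressed list. In chip columns 11 to 20 it was 4, with mitochondrial mRNA (0.0119) and without pyrimidine synthesis (0.143) and chaperones (0.0710). At positions listed at one time it was 11, and 11 without chip column 4, 11 with the replicate block, 10 with equal cell numbers, 15 with the mean of log2 over cells and 14 with fry. At positions listed at both times it was 1, and 1 with the replicate block, 0 with the estimated correlation and 0 with fry. The one-carbon list passed with the replicate block (adjusted p = 0.0364), with the block and fry (0.0031) and, at positions listed at one time, with fry (1.9e-04), equal cell numbers (0.0493) and the mean of log2 over cells (0.0472). The polyamine list passed there with fry (6.2e-04) and the mean of log2 over cells (0.0426), and the purine list with fry (0.0090). Cholesterol synthesis reversed to higher there with fry (0.0166). Mitochondrial mRNA reversed to lower relative to other genes at positions listed at one time (0.0103), without chip column 4 (0.0157), with the replicate block (0.0154) and with the mean of log2 over cells (0.0426).

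With positions listed at both times the estrogen-induced list fell below the threshold, and the test of the estrogen-repressed, pyrimidine and G1/S lists had the other direction, with medians of 0.011, 0.0034 and 0.0067. All 4 had an adjusted p of 0.927 with camera, 0.981 with the estimated correlation and 0.989 with fry. With the replicate block it was 0.871 for the estrogen-induced and estrogen-repressed lists and 0.908 for pyrimidine and G1/S.

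The difference in genes detected, -16.3, was 795 at positions listed at one time. Paired by chip column it was 856 there and 26.4 at positions listed at both times. Shares of cells that differed, 0 of 20, were 3 at positions listed at one time, 3 paired by chip column and 5 with both. Levels that differed, 1 of 20, were 3 at positions listed at one time, 4 paired by chip column, 3 with both, 0 at positions listed at both times, 0 in chip columns 1 to 10 and 0 in chip columns 11 to 20. List pairs co-varying above random lists, 2 of 12, were 4 in chip columns 1 to 10, 4 with ranks within a cell and 4 with partial rho with genes detected held fixed. Pairs below random lists, 2 of 12, were 0 with ranks within a cell, 4 with partial rho and 4 at positions listed at both times. Pairs differing between the times, 2 of 6, were 4 paired by chip column, 0 in chip columns 1 to 10, 1 in chip columns 11 to 20, 0 with ranks, 0 with partial rho and 0 at positions listed at both times. Depth per cell is unknown in reads, and shares of cells listing a gene were not compared in cells matched on relative depth.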

Other observations

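The tests of one chip under both labels, of a row effect and of unequal shares, the matching on depth and the counts of other splits for single genes were chosen after the result was seen. The profiles labelled 0 h and 12 h matched at 408 of 408 positions listed at both times, and a row effect of the chip is excluded by the median correlation of 0.0019 in the same row of different columns. One chip's libraries deposited under both time labels stays open: the estrogen-induced list lay at 0.615 ± 0.068 (SE) of the way from the 0 h to the 12 h level of positions listed at one time, but those positions are less deep (0.558 and 0.846 against 1.03 and 1.05), and in cells matched on depth it differed from the 2 levels by 0.274 ± 0.251 and -0.195 ± 0.127 of that way. Reads of both chips' cells mixed in both libraries also stays open: the squared coefficient of variation of 20 abundant G2/M genes was 0.726 ± 0.058 (SE) of that at positions listed at one time, but 1.201 ± 0.171 in cells matched on depth, where mixing would put it below 1. No biological explanation was tested.

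Of 14 genes called with the column block at positions listed at both times, 3 were processed pseudogenes, which make up 2.94% of the tested genes with a type. As a class, 410 processed pseudogenes differed from protein-coding genes of like expression by a median log2 value of 0.066 ± 0.016 (SE), which is consistent with a difference in read quality or length between the 2 sets of libraries. Of 3 forms of this statistic computed, the mean gave 0.14 ± 0.016 and the median taken within each column -0.0039 ± 0.0032; the last is held near 0, since 31.01% of its pseudogene differences were 0 and 31.1% below 0, a reason found after its value was seen. Unequal shares of the 2 chips' reads would also move the estrogen-induced list, which differed by 0.0029 ± 0.0088 (SE), less than such shares would give. No biological explanation was tested for this pattern.

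In 100 splits of the columns into groups of the same sizes, 2, the real one included, gave at least the 2 genes called over all kept cells. The highest of the others gave 3. Only the real split gave 2 genes of at least 1.5-fold, with 1 as the highest of the others. Few splits thus reached these counts, but chance is not excluded for the first, which another split exceeded. Leaving out any of 24 columns left 1 gene. For the 5 lists called, 14 splits gave as many, the highest other 10, so chance is not excluded for that number by these splits, which can put columns sharing a number on one side. Among 100 splits that part every pair of columns sharing a number, the real fit on those columns gave 1 gene and the others 0. It gave 5 lists, with 5 as the highest of the others and 2 splits as large, the real one included. Fewer of those splits reached 5 lists, but another split did, so chance is not excluded for the number of lists there either.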
